A study of Mus musculus with 6 samples.

How the data were processed

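The study measured total RNA in 6 cultures of mouse CD4 T cells under Th17 polarizing conditions for 72 hours, 3 per genotype, with stranded libraries made after removal of ribosomal RNA. The single deposited table holds 54617 entries, of which 54525 are genes with versioned Ensembl identifiers and 92 are synthetic spike-in RNAs. Each of the 6 samples has a raw column of counts deposited by the authors, which were whole numbers throughout. The authors' normalized columns hold a signal, given only for entries they marked as above background (14545), which equalled the raw count divided by a single factor per sample. This was tested on all values above 5. The authors also deposited a log2 fold change and an adjusted p-value of KO over WT, and a length per gene in bases whose derivation is not stated. The submitters named STAR, featureCounts, DESeq2 and DESeq and the GRCm38.p3 build, without versions, without saying which tool made which column and without saying whether counting used the strand. Only the raw counts entered the fits. The authors' own fold changes were used for a side-by-side count.

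Samples were grouped by their titles into WT and KO, and columns were matched to samples through the header given in each sample's description. No sample was left out. Gene positions came from GENCODE M21 on GRCm38, a copy that may differ from the annotation the authors used. It placed 99.9% of the gene identifiers (54488), and 98.6% of symbols were as in its name table. Totals ran from 36011906 to 43141474 counts per library. A gene with 0 counts in a library allows up to 3 counts, which is 0.0697 to 0.0835 CPM of the gene counts depending on the library. Spike-in RNA took from 0.161% of counts in KO replicate 1 (Wilson 95% interval 0.159% to 0.162%) to 0.216% in WT replicate 1 (0.215% to 0.218%). These binomial intervals and the floors cover counting error only, since reads without molecular identifiers are not independent molecules.

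Spike-in entries were removed before the fits. Genes were kept by filterByExpr of edgeR (minimum count 10, minimum total count 15, with the group), which left 16006 genes holding 99.9% of gene counts. Libraries were scaled by TMM, with factors from 0.946 to 0.983 in WT and from 1.03 to 1.04 in KO. The edgeR quasi-likelihood test with genotype as the only term gave each gene a log2 fold change and a p. This p was adjusted by Benjamini-Hochberg over all tested genes, and a gene was called at an adjusted p under 0.05. The SE was derived as the absolute coefficient without prior counts, divided by the square root of the F statistic of that test. Fold changes against a group at 0 in all its libraries were replaced by bounds against 3 counts over the 3 libraries of that group (0.0257 CPM in WT). The level of Prmt5 was also compared by an exact permutation test over the 10 splits of the 6 samples, two-sided. Principal components were taken from log2 CPM with a prior count of 2.

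Before the data were examined, 33 gene lists were fixed. They covered cholesterol biosynthesis, SREBP control and sterol uptake, cholesterol efflux and esterification, and fatty acid synthesis. They further covered the Th17, Th1, Th2 and Treg programmes, naive and memory T cell genes, common gamma chain cytokine signalling, T cell activation, the methylosome, other arginine methyltransferases, and Sm proteins with snRNP assembly. Further lists were S phase and DNA replication, G2 and mitosis, p53 targets, the integrated stress response, the type I interferon response, glycolysis and nuclear encoded oxidative phosphorylation. Cell type lists covered T cells, CD8 T cells, NK and innate lymphoid cells, gamma delta T cells, B cells, myeloid and dendritic cells, granulocytes and mast cells, erythroid cells and stromal cells. The last lists were mitochondrially encoded mRNAs, ribosomal proteins and replication-dependent histones. Lists with at least 3 tested members (31) were tested by camera with its preset correlation of 0.01, adjusted over the lists, and again with a correlation estimated for each list. The CD8 list, with 2 tested members, and the erythroid list, with 0, were not tested as sets. Some programme genes stand in 2 lists, and no cell type marker stands in another list.

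The genes named in the text followed a rule fixed at the same time. It took Prmt5, 21 genes chosen for the question whatever their value, the 8 largest rises and the 8 largest falls, and up to 4 members of each list with the lowest p. The rises and falls were taken among called genes with a mean of at least 5 CPM, no overlap between groups and an assigned symbol. Any other gene is said to be chosen after its values were seen. Some genes the rule takes are not reported here.

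Alternatives fixed before the data were examined were DESeq2, RLE and upper-quartile scaling, limma-voom, no filter, a filter at a mean of 1 CPM, removal of mitochondrial, structural RNA and histone genes, each library left out in turn, the replicate number as a block, and a minimum absolute log2 fold change of 1. For the lists they were the estimated correlation, fry in its directional and mixed forms, and a rank test on the DESeq2 statistic. Chosen after seeing the data were a correction for GC content and transcript length by natural splines with 5 degrees of freedom (99.9% of tested genes had both values), the same with the replicate block, spike-in scaling, KO replicate 2 as the only KO library, the Y-linked level as a covariate, and removal of X- and Y-linked genes.

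The steps were tested on simulated data of the same size, in which 200 genes differed. The test recovered 29.9% of 67 genes changed 1.5-fold, 70.1% of 67 changed 2-fold and 95.5% of 66 changed 4-fold, and it called 8 of 15806 unchanged genes. A list of 20 genes lowered 1.5-fold had a camera adjusted p of 1.06e-14, or 0.0277 with an estimated correlation, and 0 of 30 random lists were called. Simulated genes varied independently of one another, whereas the correlation estimated in the real data was 0.310 for cholesterol biosynthesis and 0.189 for the Th17 programme. The simulation therefore does not show how often camera calls lists of correlated genes by error. Its 200 changed genes were also far fewer than the 6809 called in the real data. Adjustment over all genes was therefore stricter in the simulation, and the recovered shares do not carry over to the real comparison. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and version 1.17.8 of data.table, with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.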

Results

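RNA sequencing measured the total RNA of 6 mouse T cell cultures. Naive CD4 T cells of C57BL/6 mice, taken from spleens and lymph nodes, were stimulated for 72 hours through CD3 and CD28 with TGFβ and IL-6, cytokines that drive CD4 T cells toward the Th17 type. The WT group held 3 cultures with the genotype label iCD4-PRMT5fl/fl, and the KO group held 3 cultures labelled iCD4-PRMT5delta/delta. Prmt5 encodes the enzyme that makes most of the symmetric dimethylarginine on proteins, among them histones and splicing factors. The deposited counts summed to 36011906, 43141474 and 42543115 in WT replicates 1, 2 and 3, and to 40350422, 36489789 and 41467126 in KO replicates 1, 2 and 3. Levels are counts-per-million values (CPM) after TMM scaling, given as mean ± SD over 3 libraries. Log2 changes are KO over WT with an SE derived from the edgeR test. Floors cover counting error only, while the SE and interval of a log2 change come from the edgeR fit and include the spread between replicates. The single comparison of the study is KO against WT, and from the title it asks how PRMT5 bears on cholesterol biosynthesis and Th17 responses.

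Prmt5 itself (ENSMUSG00000023110.12, GRCm38 chromosome 14, 54507187 to 54517525, minus strand) fell from 121 ± 14.0 CPM in WT to 49.7 ± 5.11 CPM in KO. The KO mean was 41.0% of the WT mean, a log2 change of -1.29 ± 0.11 (95% interval -1.54 to -1.03), with an edgeR adjusted p of 0.00012. Single WT libraries stood at 109, 137 and 118 CPM, and single KO libraries at 52.4, 43.8 and 52.9 CPM. The two-sided exact permutation test on these 6 values gave p = 0.1, the smallest that 3 against 3 samples allow. The labels do not say which exons were deleted, and the counts are summed over the whole gene.

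The cells differed broadly between genotypes. Of 16006 genes tested, 6809 were called (42.5%), with 3466 higher and 3343 lower in KO, and 2334 of them differed by a log2 change of at least 1 (1490 higher, 844 lower). The even split depended on the scaling, with 3085 higher and 1363 lower under spike-in scaling. All 3 KO libraries lay beyond all 3 WT libraries for 6777 of the called genes and for 55.6% of tested genes, where chance gives 10%. Each called gene named here showed its direction in 3 of 3 KO libraries, with no overlap between the groups. The first principal component held 75.3% of the variance and parted the genotypes, and the next, with 9.53%, set WT replicate 2 apart from WT replicates 1 and 3. Reads of 4 Y-linked genes were counted in all 3 KO libraries and in no WT library, so the sex of the cells was not balanced between genotypes. The count of called genes was 2752 with KO replicate 2 as the only KO library, 3460 with the Y-linked level as a covariate and 4448 with spike-in scaling, all alternatives chosen after seeing the data. Among the named genes, the single KO library and the covariate each ended the calls of Srebf1, Il17a, Tbx21, Foxp3, Prmt2, Prmt3, Prmt9, Gemin8, Cd8a and Ms4a1, the single KO library also those of Nr1h3, mt-Nd6 and Cd8b1, and the covariate also that of Lck. Apart from Prmt2, the log2 changes of these genes there were 71.4% to 135% of those with all 6 libraries and no covariate. These alternatives are not separate checks. The relative Y-linked level was 0 in the WT libraries and 0.97, 0.13 and 1 in KO replicates 1, 2 and 3. With the covariate the genotype difference therefore also rests mainly on KO replicate 2. The column names carry 1 number for each WT library (30, 42, 52) and 2 for each KO library (36, 39 and 53, each joined to 51), with no statement of their meaning. If 51 is an animal that all KO cultures shared, the KO libraries were not independent and the p-values here are too small.

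Genes of cholesterol synthesis were lower in KO throughout the pathway. All 21 tested genes of the cholesterol biosynthesis list fell, and 21 also fell when adjusted over the list alone, with a median log2 change of -0.82. The camera test of the list gave an adjusted p of 6.36e-14, and an adjusted p = 0.245 with an estimated correlation. The study names this pathway in its title, so the list is not independent evidence of its direction. Hmgcs1, which condenses acetoacetyl-CoA with acetyl-CoA early in the pathway (ENSMUSG00000093930.2, chromosome 13, 119690379 to 119708260), fell from 339 ± 31.8 to 158 ± 7.84 CPM (log2 -1.10 ± 0.08, edgeR adjusted p = 5.97e-05). Lss, lanosterol synthase, fell from 145 ± 7.13 to 63.9 ± 5.84 CPM. Log2 changes were -1.22 ± 0.09 for Fdps, -1.08 ± 0.07 for Acat2, -0.90 ± 0.07 for the squalene epoxidase gene Sqle and -0.68 ± 0.06 for Cyp51.

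Regulators and transporters of sterols split. In the list of SREBP control and sterol uptake, 5 of 12 tested genes fell and 1 rose, the same counts when adjusted over the list alone. Its camera adjusted p was 0.0216, with a median log2 change of -0.19, and its adjusted p = 0.331 with an estimated correlation. The list also lost its call with the rank test on the DESeq2 statistic (adjusted p = 0.0697) and with camera under spike-in scaling (adjusted p = 0.0679). The log2 change was -1.02 ± 0.05 for Insig1 and -1.26 ± 0.10 for Stard4. Srebf1 fell by 0.60 on the log2 scale (SE 0.15, edgeR adjusted p = 0.0136), a call lost without KO replicate 1 (0.0643). Srebf2, the main activator of sterol synthesis genes, was not called, with log2 -0.34 ± 0.20 and an edgeR adjusted p of 0.207. Its change was -0.55 without WT replicate 2 (adjusted p = 0.0062) and -0.11 without WT replicate 1 (adjusted p = 0.584). Among 8 tested genes of cholesterol efflux and esterification, 3 rose and 1 fell, also when adjusted over the list alone, and the list was not called (median log2 0.15, camera adjusted p = 0.255). The efflux pump gene Abca1 rose from 28.3 ± 1.74 to 78.0 ± 9.81 CPM. Nr1h3, which encodes the oxysterol receptor LXRα, was low in both groups and rose from 0.79 ± 0.07 to 1.60 ± 0.08 CPM (log2 1.02 ± 0.18). Which cells carried Nr1h3 was not tested. Of 13 tested genes of fatty acid synthesis 8 fell, 8 also when adjusted over the list alone, with a median log2 change of -0.71. Camera gave this list an adjusted p of 5.40e-05, and an adjusted p = 0.245 with an estimated correlation. Acly, which supplies cytosolic acetyl-CoA, fell from 868 ± 63.5 to 496 ± 15.4 CPM, and the desaturase genes Fads1 and Fads2 fell by 1.26 and decreased by 1.85 on the log2 scale.

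The Th17 programme was lower in KO, led by Il17f and the receptors for IL-23 and IL-1. In that list 11 of 19 tested genes fell and 3 rose, or 13 and 3 adjusted over the list alone, with a median log2 change of -0.92. Its camera adjusted p was 3.04e-07, and its adjusted p = 0.245 with an estimated correlation. Il17f (ENSMUSG00000041872.9, chromosome 1, 20777146 to 20790617) fell from 338 ± 56.9 to 15.6 ± 0.93 CPM (log2 -4.44 ± 0.14, edgeR adjusted p = 6.58e-06). Il1r1 fell from 21.7 ± 5.87 to 1.15 ± 0.23 CPM, and Il23r from 20.7 ± 2.82 to 1.16 ± 0.49 CPM. Il21, a cytokine that sustains Th17 cells, fell from 564 ± 32.7 to 235 ± 14.3 CPM, and the transcription factor gene Irf4 from 1516 ± 163 to 540 ± 13.5 CPM. Il17a, the signature cytokine, was low in both groups and fell from 7.35 ± 1.24 to 4.38 ± 0.36 CPM (edgeR adjusted p = 0.0071). That call was lost with KO replicate 2 as the only KO library (log2 -0.84, adjusted p = 0.0893) and with the Y-linked covariate (-0.88, 0.0679). The 3 members that rose, chosen after their values were seen, were the nuclear receptor gene Rora (log2 1.29), the chemokine receptor gene Ccr6 (1.56) and Tmem176b (1.11).

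**Figure D1:**
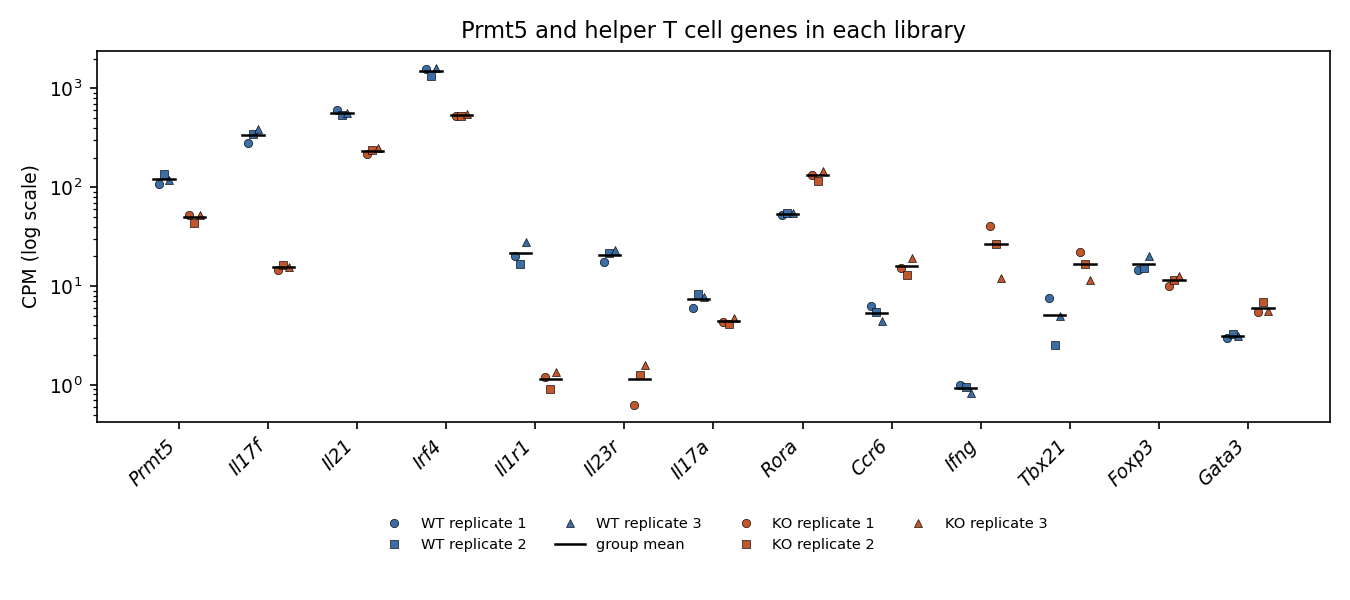
Points give CPM of each library on a log axis for Prmt5 and 12 helper T cell genes, blue for WT and orange for KO, with a marker shape per replicate and a bar at the mean of 3 libraries. Il17f, Il1r1 and Il23r show the widest falls and Ifng the widest rise.

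Genes of other helper T cell types moved in both directions. Of 13 tested Th1 genes 5 rose and 3 fell, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.759). Its median log2 change of -0.02 was opposite in sign to its mean of 0.35 and turned positive with upper-quartile and spike-in scaling and with the GC content and length correction. Ifng, the main Th1 cytokine (ENSMUSG00000055170.4, chromosome 10, 118441046 to 118445892), rose from 0.93 ± 0.08 CPM in WT to 40.6, 26.9 and 12.0 CPM in KO replicates 1, 2 and 3 (log2 4.84 ± 0.47, edgeR adjusted p = 0.000218). The Th1 regulators Tbx21 and Eomes rose by log2 1.73 ± 0.39 and 1.71 ± 0.21. Ifng, Tbx21 and Eomes were all lowest in KO replicate 3 among the KO libraries, as were 7 of the 8 gamma delta, CD8 and NK markers called higher, against 34.8% of all genes called higher, an order looked at after the values were seen. Of 8 tested Th2 genes 4 rose and 1 fell, or 5 and 1 adjusted over the list alone (median log2 0.89, camera adjusted p = 0.773). Gata3 rose from 3.12 ± 0.13 to 5.97 ± 0.77 CPM, and Ccr4 fell by 1.99 on the log2 scale. In the Treg list 9 of 15 genes fell and 2 rose, also when adjusted over the list alone, with a median log2 change of -0.54. Camera gave an adjusted p of 0.0217, and an adjusted p = 0.486 with an estimated correlation. Il2ra and Lrrc32 fell by 1.17 and decreased by 1.78 on the log2 scale, whereas Ikzf2 rose from 9.07 ± 1.62 to 68.9 ± 13.4 CPM and the integrin gene Itgae from 7.63 ± 2.72 to 97.7 ± 5.06 CPM. Foxp3, the defining Treg factor, fell by 0.54 on the log2 scale (SE 0.15, edgeR adjusted p = 0.0243). That call was lost without WT replicate 3 (0.0693), KO replicate 1 (0.0961) or KO replicate 2 (0.0671).

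Among 12 naive and memory T cell genes 7 rose and 2 fell (median log2 0.39, camera adjusted p = 0.176), and Id3 and Tcf7 rose by log2 1.18 ± 0.11 and 0.81 ± 0.10. Among 13 T cell activation genes 7 rose and 3 fell (median log2 0.53, camera adjusted p = 0.453). The costimulatory receptor gene Icos fell from 582 ± 45.1 to 145 ± 11.7 CPM and Myc by 0.75 on the log2 scale, while Nr4a1 rose by log2 1.27 ± 0.11. Of 12 genes of common gamma chain cytokine signalling 2 rose and 5 fell, with a camera adjusted p of 0.0841. Their median log2 change of -0.06 was opposite in sign to the mean of 0.08 and turned positive with spike-in scaling. Il4ra fell from 936 ± 101 to 309 ± 6.15 CPM. Neither Il2rg, the shared receptor chain (log2 0.04 ± 0.07, edgeR adjusted p = 0.717), nor Il7r (log2 0.12 ± 0.10, edgeR adjusted p = 0.393) was called. In these 3 lists the counts were the same when adjusted over the list alone.

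Proliferation genes were lower and p53 target genes higher in KO. In the S phase and DNA replication list 20 of 25 genes fell and 1 rose, or 21 and 1 adjusted over the list alone (median log2 -0.35). Camera gave an adjusted p of 0.00195, and an adjusted p = 0.518 with an estimated correlation. In the G2 and mitosis list 21 of 23 genes fell, or 22 adjusted over the list alone (median log2 -0.52), with a camera adjusted p of 5.59e-07 and an adjusted p = 0.331 with an estimated correlation. Mcm7, a subunit of the replicative helicase, fell from 452 ± 12.8 to 328 ± 6.83 CPM, Top2a from 2928 ± 120 to 1688 ± 131 CPM and Ccna2 from 510 ± 21.1 to 343 ± 14.6 CPM. Of 67 tested replication-dependent histone genes 59 fell and 2 rose, or 61 and 2 adjusted over the list alone (median log2 -0.66). Camera gave an adjusted p of 2.83e-20, and an adjusted p = 0.245 with an estimated correlation. Single histone genes have near-identical copies, and how reads with several positions were counted is not stated.

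Of 24 tested p53 targets 20 rose and none fell, or 20 and 1 adjusted over the list alone, with a median log2 change of 1.09. Its camera adjusted p was 3.83e-18, and its adjusted p = 0.181 with an estimated correlation. Ccng1 (ENSMUSG00000020326.7, chromosome 11, 40748552 to 40755311) rose from 317 ± 7.46 to 813 ± 9.02 CPM (log2 1.36 ± 0.04, edgeR adjusted p = 6.92e-06). Phlda3 rose from 7.94 ± 0.56 to 59.8 ± 6.01 CPM, Zmat3 from 6.43 ± 0.51 to 25.9 ± 0.19 CPM and the death receptor gene Fas from 73.4 ± 3.85 to 160 ± 6.76 CPM. The cell cycle inhibitor gene Cdkn1a rose by log2 1.65 ± 0.18. Mdm2 and Mdm4, whose products restrain p53, rose by log2 0.56 ± 0.06 and 0.47 ± 0.06. Of 17 genes of the integrated stress response 8 fell and 1 rose, also when adjusted over the list alone (median log2 -0.35), with a camera adjusted p of 0.0217 and an adjusted p = 0.439 with an estimated correlation. Trib3 fell from 19.1 ± 1.02 to 4.26 ± 0.49 CPM, and Sesn2, which p53 also controls, rose by log2 1.43 ± 0.17. In the type I interferon response list 12 of 19 genes rose and none fell, or 13 and 0 adjusted over the list alone (median log2 0.85). Camera gave an adjusted p of 0.000118, and an adjusted p = 0.439 with an estimated correlation. The RNA sensor gene Ifih1 rose from 6.80 ± 1.25 to 27.5 ± 1.62 CPM, Mx1 by log2 2.90 ± 0.28 and Usp18 by log2 1.87 ± 0.25. Mx1 and Usp18 were lowest in KO replicate 3 among the KO libraries, as Ifng was, and Ifih1 was not. This order was looked at after the values were seen.

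Nearly all glycolysis genes were lower in KO. Of 19 genes 18 fell and none rose, also when adjusted over the list alone, with a median log2 change of -0.97. Camera gave an adjusted p of 6.54e-10, and an adjusted p = 0.245 with an estimated correlation. Aldoa fell from 1283 ± 33.7 to 657 ± 12.8 CPM, Pgk1 from 3229 ± 100 to 1627 ± 163 CPM, the lactate exporter gene Slc16a3 from 356 ± 19.1 to 164 ± 18.0 CPM and Hk2 from 358 ± 41.6 to 174 ± 9.11 CPM. Of 20 nuclear genes of oxidative phosphorylation 7 fell and 13 were not called, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.187). Its median log2 change of -0.09 turned to 0.05 with spike-in scaling.

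**Figure D2:**
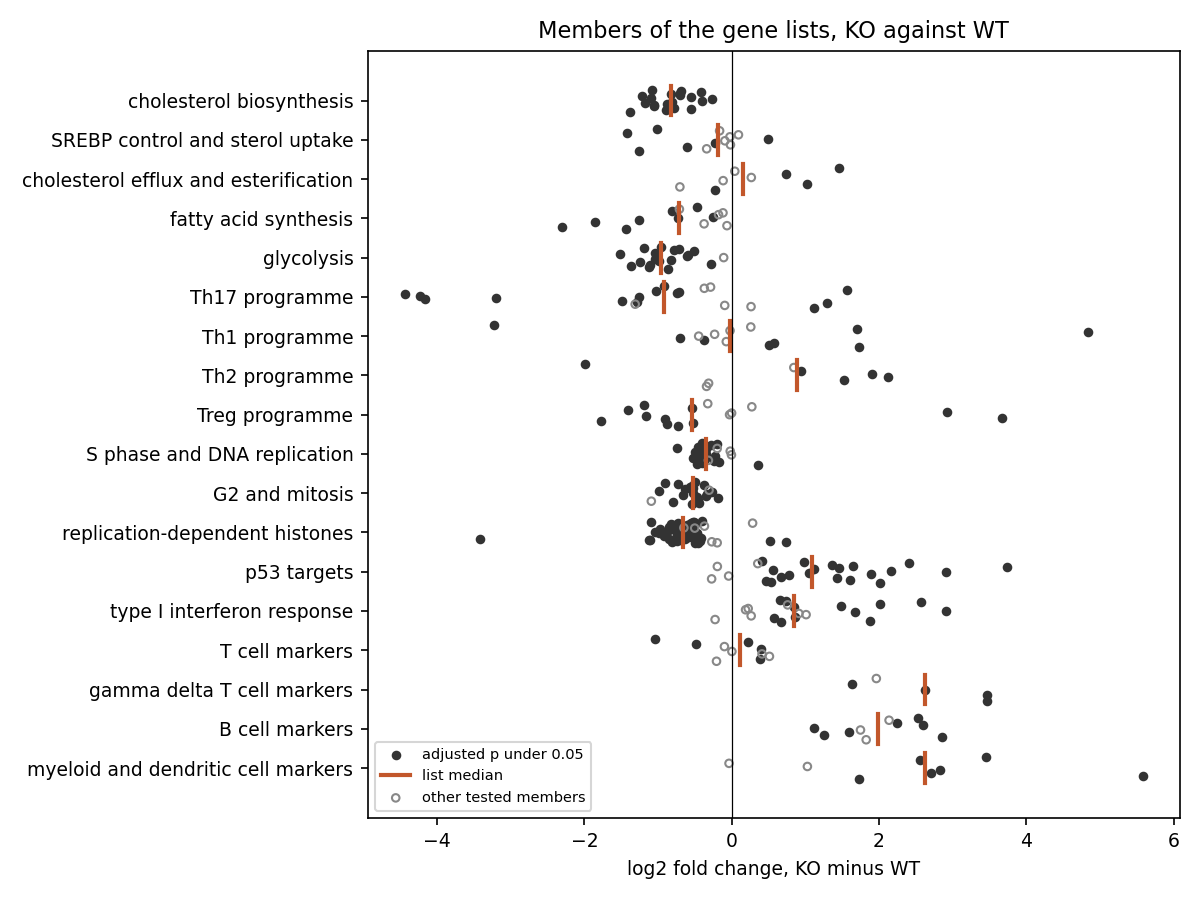
Each point is a tested member of a list, placed by its log2 change of KO over WT, filled where the edgeR adjusted p was under 0.05 and open elsewhere, with an orange bar at the list median. Medians lie at -0.82 for cholesterol biosynthesis, -0.97 for glycolysis, -0.92 for the Th17 programme and 1.09 for p53 targets, and the Th1 median of -0.02 changes sign with scaling.

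In the methylosome list of 5 genes Prmt5 alone was called (camera adjusted p = 0.355), and the median log2 change of -0.02 turned positive with upper-quartile and spike-in scaling. Of 7 other arginine methyltransferase genes 1 rose and 2 fell (median log2 -0.20, camera adjusted p = 0.531). These were Prmt2, which rose by log2 0.80 ± 0.18, and Prmt9 and Prmt3, which fell by 0.37 and decreased by 0.29 on the log2 scale. All 3 calls were lost with KO replicate 2 as the only KO library and with the Y-linked covariate, where the log2 change of Prmt2 was 0.47 (adjusted p = 0.233) and 0.40 (adjusted p = 0.258), that of Prmt9 -0.32 and -0.31, and that of Prmt3 -0.27 and -0.28. For both lists the counts were the same when adjusted over the list alone. Sm proteins are spliceosome core proteins, some of which PRMT5 methylates. Of 19 genes for Sm proteins and snRNP assembly, 2 rose and 5 fell, or 0 and 4 adjusted over the list alone (camera adjusted p = 0.417), while 42.5% of all tested genes were called. The list's median log2 change of -0.04 turned positive with upper-quartile and spike-in scaling. Gemin8 and Lsm4 fell by 0.72 and decreased by 0.54 on the log2 scale. Among transcripts that track RNA handling, 1 of 12 tested mitochondrially encoded mRNAs fell (camera adjusted p = 0.918), also when adjusted over the list alone, with a median log2 change of 0.05 that turned negative with the GC content and length correction. That gene, mt-Nd6, fell by 0.80 on the log2 scale, a call lost without KO replicate 2 (adjusted p = 0.0512). Of 82 tested ribosomal protein genes 3 rose and 25 fell, or 3 and 15 adjusted over the list alone (camera adjusted p = 0.103), and their median log2 change of -0.12 turned to 0.01 with spike-in scaling. Spike-in scaling moved the median of all tested genes by 0.14.

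Transcripts of other cell types were more abundant in the KO libraries. Of all 16006 tested genes 3466 were called higher. Of 63 markers of other cell types in 8 lists, 35 were tested, of which 27 were higher and 2 lower in KO. A marker near 0 in WT was tested only if the KO libraries had enough counts. The camera tests of these lists and the tested markers therefore lean toward higher in KO. With KO replicate 2 as the only KO library 14 were called higher. Of 5 tested gamma delta T cell markers 4 rose, or 5 adjusted over the list alone (median log2 2.63), with a camera adjusted p of 2.01e-05 and an adjusted p = 0.245 with an estimated correlation. The constant region genes Tcrg-C4 and Trdc rose from 2.21 ± 0.61 to 24.3 ± 6.04 CPM and from 0.67 ± 0.30 to 7.40 ± 1.58 CPM. Both CD8 T cell markers rose, 2 also when adjusted over the list alone, Cd8a by log2 1.85 ± 0.39 and Cd8b1 by log2 1.05 ± 0.14. Of 3 tested NK and innate lymphoid markers Gzma and Klrk1 rose by log2 1.77 ± 0.23 and 1.49 ± 0.31 and Klre1 fell by 2.22, with the same counts adjusted over the list alone (camera adjusted p = 0.759). Of 10 B cell markers 7 rose, or 10 adjusted over the list alone (median log2 1.98), with a camera adjusted p of 0.00519 and an adjusted p = 0.519 with an estimated correlation. Ighm rose from 123 ± 15.6 to 292 ± 66.6 CPM and Ms4a1, which encodes CD20, from 2.19 ± 1.59 to 15.8 ± 7.13 CPM. Of 8 tested myeloid and dendritic cell markers 6 rose, also when adjusted over the list alone (median log2 2.63), with a camera adjusted p of 0.00519 and an adjusted p = 0.355 with an estimated correlation. The list lost its call at a mean of at least 1 CPM (adjusted p = 0.228).

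The mast cell and basophil protease genes Mcpt8 and Prss34 and a further mast cell gene, Cpa3, rose. Prss34 went from 0.10 ± 0.09 to 12.8 ± 9.78 CPM and Mcpt8 from 0.10 ± 0.17 to 10.3 ± 8.42 CPM, with wide spread among the KO libraries and all WT reads of Mcpt8 in WT replicate 3. Ly6g, a neutrophil surface marker gene, fell from 29.98 ± 17.4 to 0.21 ± 0.10 CPM. These were the 3 risers and the 1 faller among 4 tested granulocyte and mast cell markers, also when adjusted over the list alone (camera adjusted p = 0.453). All 3 tested stromal markers rose, also when adjusted over the list alone (median log2 1.33, camera adjusted p = 0.0816). Only 1 of them reached a mean of 1 CPM in WT, at 135 ± 8.48 CPM against 210 ± 19.6 CPM in KO. The others stayed under 1 CPM in both groups, so these values do not show stromal cells in KO. No erythroid marker of 6 was tested. T cell markers split, with 3 of 10 higher and 2 lower, or 4 and 3 adjusted over the list alone. Their median log2 change was 0.11 and their mean 0.01, while camera pointed down (adjusted p = 0.773). Lck rose by log2 0.39 ± 0.06, and Cd2 fell by 1.04 on the log2 scale.

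The largest rises by the naming rule were the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty, followed by Prss34, Ccl6, Mcpt8 and Lyz2. Against the floor of 3 counts over the 3 WT libraries, all at 0, Ddx3y was at least 8454-fold higher in KO, Kdm5d at least 3039-fold, Eif2s3y at least 2314-fold and Uty at least 2098-fold. With limma-voom Ddx3y (adjusted p = 0.0698) and Kdm5d (adjusted p = 0.0526) were not called. In KO replicate 2 these genes were much lower, as with Ddx3y at 38.3 CPM against 302 and 311 CPM in KO replicates 1 and 3. Xist, transcribed from the inactive X chromosome and chosen after its values were seen, stood at 395, 416 and 389 CPM in WT replicates 1, 2 and 3, at 479 CPM in KO replicate 2, at 0.02 CPM (1 read) in KO replicate 1 and at 0 in KO replicate 3. The chemokine gene Ccl6 rose from 0.18 ± 0.15 to 19.7 ± 14.0 CPM and Lyz2, a myeloid lysozyme gene, from 0.24 ± 0.21 to 11.3 ± 10.1 CPM. The largest falls were those of Slc38a4, an amino acid transporter gene (log2 -7.90 ± 0.27), Ly6g (-7.17 ± 0.59), Gap43 (-5.96 ± 0.18), the chemokine receptor gene Cxcr2 (-5.22 ± 0.36), Serpinb1a (-4.66 ± 0.32), Serpinb5 (-4.54 ± 0.28), Tgfb3 (-4.52 ± 0.33) and Il17f. Slc38a4 went from 14.3 ± 1.57 to 0.056 ± 0.034 CPM.

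Of 31 lists tested, camera with its preset correlation called 15, 5 higher and 10 lower in KO. With an estimated correlation none was called, and 6 had an unadjusted p under 0.05. The fry test, which asks whether the genes of a list move on balance one way, called 23 lists, and its mixed form, which asks whether they change in either direction, called all 31. Neither form compares a list with other genes. The authors' deposited table, with an adjusted p for 14509 genes, held 6656 called genes, 3389 higher and 3267 lower in KO. Of these, 6312 were also called here, all 6312 with the same sign.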

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

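The tests chosen only after the results were seen were the GC content and length correction, with and without the replicate block, spike-in scaling, KO replicate 2 as the only KO library, the Y-linked level as a covariate and the removal of X- and Y-linked genes. The count of called genes, 6809, lay between 5203 and 7033 when single libraries were left out, the lowest without KO replicate 1. It was 6850 with DESeq2, 6842 with limma-voom, 6827 and 6734 with RLE and upper-quartile scaling, 7442 with no filter, 5809 at a mean of 1 CPM, 6703 without mitochondrial, structural RNA and histone genes, 6814 with the GC content and length correction and 6604 without X- and Y-linked genes. It was 2334 with an absolute log2 fold change of at least 1, a stricter rule by construction, and 2752 with KO replicate 2 as the only KO library, which leaves fewer samples and assumes that this library varies like the others. It was 3460 with the Y-linked level as a covariate, a fit that also rests mainly on KO replicate 2. With spike-in scaling it was 4448, where 3085 genes (69.4%) were higher against 50.9% under TMM, and the cause was not tested. The replicate block gave 6190 genes, of which 5968 were also among the 6809 with the same sign (87.6%), and 6255 together with the GC content and length correction. The number in the titles gave no clear sign of pairing. The correlations of same-numbered libraries across genes, after group means were removed, were -0.02, 0.01 and 0.08. Those of the other pairs ran from -0.06 to 0.05. With 3 libraries per group these values cannot exclude a pairing.

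Prmt5 ranged from -1.36 to -1.20 when single libraries were left out, and stayed called. The adjusted p of the cholesterol biosynthesis list ranged from 4.90e-15 to 3.20e-12 and that of the Th17 programme list from 6.38e-08 to 0.000261 without single libraries. Both rose to 0.245 with an estimated correlation (unadjusted camera p 0.0332 and 0.0475), a value that several lists shared after adjustment. The estimated correlation was 0.310 for cholesterol biosynthesis and 0.189 for the Th17 programme against the preset 0.01. A higher correlation was not the only source of such rises. For stromal markers, with an estimated correlation of -0.124, the unadjusted camera p also rose, from 0.0421 to 0.109. Of the other lists 13 were called, from 13 to 15 without single libraries, 0 with an estimated correlation, 21 and 29 with fry in its directional and mixed forms, and 16 with the replicate block. The SREBP list lost its call with the rank test (adjusted p = 0.0697) and spike-in scaling (0.0679), the integrated stress response list with the GC content and length correction (0.0558) and spike-in scaling (0.0881), the Treg list with spike-in scaling (0.256) and the Y-linked covariate (0.0518), and the myeloid list at a mean of 1 CPM (0.228). Calls were gained by ribosomal proteins (rank test 0.000205, replicate block 0.0382, without WT replicate 1 0.0218, without KO replicate 2 0.00659), stromal markers (block 0.0382, without KO replicate 1, 2 or 3 0.0358, 0.0464 and 0.0464, Y-linked covariate 0.0470), granulocyte and mast cell markers (block 0.0132, without KO replicate 3 0.0319, spike-in scaling 0.000128, KO replicate 2 as the only KO library 0.0470), common gamma chain signalling (a mean of 1 CPM 0.0496, without WT replicate 2 0.0429), oxidative phosphorylation (rank test 0.0285) and naive and memory genes (Y-linked covariate 0.0470). Markers of other cell types called higher numbered 27, from 23 to 34 without single libraries and 14 with KO replicate 2 as the only KO library. Of the 99 genes named besides Prmt5, 99 kept direction and side of the threshold with DESeq2, RLE scaling, the replicate block and the GC content and length correction, 96 with limma-voom (2 lost, 1 gained), 86 with KO replicate 2 as the only KO library and 87 with the Y-linked covariate. Leaving out single libraries ended at most 2 of their calls at a time (Foxp3, Srebf1 and mt-Nd6 in the report) and started those of Srebf2 and Xist. With the Y-linked covariate Xist reversed, from -1.33 (not called) to 2.49. Tested genes had a median of 2944 counts over the 6 libraries, while genes at a few counts in WT, such as Cpa3, have wide intervals.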

Other observations

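The tests chosen only after the results were seen were those of sex, of male cells in KO replicate 2, of reads passed between libraries, of B, myeloid and mast cells, and of a lower share of CD4 T cells, and the GC content and length correction was added after seeing the data, with its bound written before its result. A further 4 genes were chosen after their values were seen, so their shared direction is no test of a cell type, and the fixed NK and innate lymphoid list was not called (camera adjusted p = 0.759), with its member Klre1 lower in KO. The chemokine gene Xcl1 rose from 1.37 ± 0.12 to 58.5 ± 8.88 CPM, Gzmb by log2 1.75, Nkg7 by log2 2.55 and the interferon-induced gene Gbp10 by log2 5.34. Ly6g and Cxcr2, both known from neutrophils, had 3579 and 2606 reads over the 3 WT libraries and 25 and 73 over the 3 KO libraries. The abundant neutrophil transcripts S100a8 and S100a9, listed markers with too few counts to be tested and chosen here after their values were seen, had 0 reads in WT, where the floor is 3 counts, and 13 and 19 reads in KO.

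Counts by annotated gene class were looked at after the data were seen and were not tested for enrichment. Of 807 tested genes of the class TEC, which await experimental evidence, 167 were higher and 47 lower, with a median log2 change of 0.28, which was 0.16 after the GC content and length correction. Of 125 sense intronic genes 22 were higher and 3 lower, with a median of 0.24, or 0.10 after that correction. Of protein-coding genes 2863 were higher and 2956 lower (median -0.01), but 3199 and 2567 with upper-quartile scaling (median 0.04) and 2444 and 1149 with spike-in scaling (median 0.12). Whether counting used the strand is not stated.

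The broad expression difference between KO and WT was weighed against trends on GC content and length and against sex. After each library's trend on GC content and transcript length was removed, 92.1% of the 6809 called genes were still called in the same direction, which argues against such a trend as the whole cause. A set of 2080 autosomal genes was picked as called without KO replicate 2 at an absolute log2 change of at least 1. Their changes were measured against the same WT libraries. Over this set KO replicate 2, with Xist at the WT level, showed a median of 94.3% (interquartile range 78.6 to 107) of the change of KO replicates 1 and 3, and 2077 genes kept their direction. Its Y-linked level would give 19.0% (9.09 to 23.4). With separate controls, KO replicates 1 and 3 against 2 WT libraries and KO replicate 2 against the remaining one, the medians were 83.7%, 93.8% and 92.9%. Since only 1 KO library had Xist at the WT level, sex and genotype cannot be told apart by this test, and both sex and loss of Prmt5 may contribute, as may an animal shared by the KO cultures.

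The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For each of 4 results only 1 split, the real one, reached the real value: 6809 called genes against a highest other of 0 (60 to 332 genes at an unadjusted p under 0.05 by edgeR), 15 called lists against 14, a camera p of 6.15e-15 for cholesterol biosynthesis against 1.27e-09, and 4.90e-08 for the Th17 programme against 7.03e-07. The other splits called 5 to 14 lists with 0 genes called. Each of them sets 2 WT and 1 KO library against 1 WT and 2 KO libraries, so part of the genotype difference remains in each. The rest of that difference adds to the spread within both groups, which lowers the number of genes called. The 0 called genes of the other splits were thus nearly fixed in advance and are no measure of chance.

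The Y-linked genes were followed up in KO replicate 2. The 4 genes stood there at 12.5% to 14.0% of their level in KO replicates 1 and 3, a median of 13.2% with a ratio of highest to lowest of 1.12, while Xist was at 120% of the WT mean. One common share of male cells mixed into a female culture may explain this, and a candidate source is whatever the number 51 stands for in all KO column names. Reads passed between libraries during sequencing are argued against, since Xist in KO replicates 1 and 3 reached no more than 0.0060% of the WT mean and no Y-linked read was counted in WT.

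Transcripts of other cell types were higher in KO although naive CD4 T cells had been isolated. Of 16 members of the B cell, myeloid and granulocyte or mast cell lists called higher, 14 (87.5%) were highest in KO replicate 3 among the KO libraries, against 37.3% of all 3466 genes called higher. Ly6g, the only member of these lists called lower, is not in this count, and stood highest in KO replicate 2 (0.318 CPM). B cells, myeloid cells and mast cells or basophils carried over into the KO cultures may explain this shared order. In KO Ms4a1 stood at 15.8 ± 7.13, Lyz2 at 11.3 ± 10.1 and Prss34 at 12.8 ± 9.78 CPM. Ighm, at 292 ± 66.6 CPM in KO, already stood at 123 ± 15.6 CPM in WT, where Ms4a1 was at 2.19 ± 1.59 CPM. The KO level of Ighm is therefore no measure of carried-over B cells. In these 3 lists 6 of 10, 3 of 14 and 1 of 10 members stood at a mean of at least 1 CPM in WT. A lower share of CD4 T cells alone would raise markers of every type by about the same amount in each KO library. The ratio of KO replicate 3 to the mean of KO replicates 1 and 2 had a median of 0.633 (interquartile range 0.589 to 0.660) over 4 gamma delta T cell markers. It was 1.84 (1.56 to 2.17) over 7 B cell, 1.58 (1.25 to 2.39) over 6 myeloid and 3.67 (3.51 to 4.93) over 3 granulocyte and mast cell markers. These values argue against that explanation for these markers, all picked for being called higher. The ranges are over genes, not replicates, and KO replicate 3 is 1 library. Which cells carried Ifng and the gamma delta, CD8 and NK transcripts was not tested.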
